A study of Homo sapiens with 4 samples.

How the data were processed

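A total of 4 groups of human 293 tet-On cells were compared, with 1 array per group. The groups were a clone carrying NOR1 without doxycycline, the same clone with doxycycline, a clone carrying EWS/NOR1 without doxycycline, and that clone with doxycycline. The labels describe cells grown in DMEM with 10% fetal calf serum, total RNA purified on RNeasy columns, and biotin-labelled RNA made by in vitro transcription. Each array held 54675 probe sets, of which 62 were controls.

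The deposited values are intensity, 1 signal per probe set on a linear scale, made by the authors with GCOS, the Affymetrix array software. Its version, the target of its scaling, its detection calls and its filters are not stated in the sources used here. The deposited signals had trimmed means of 165 and 164 in the NOR1 clone without and with doxycycline, and of 150.4 and 156 in the EWS/NOR1 clone. No values were missing from these arrays and no array was left out.

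Each array was scaled to the same mean after trimming 2% of the probe sets at each end. The factors were 0.962 and 0.967 for the NOR1 clone without and with doxycycline, and 1.06 and 1.02 for the EWS/NOR1 clone. Scaled signals under a floor of 22.6, the 50th percentile of all scaled signals other than those of the controls, were set to the floor, and log2 was taken. A gene counted as measured in a comparison when at least 1 of the arrays compared lay above the floor. A ratio against an array at or under the floor is given as a bound. Bright genes were those at or above 150.0, the 75th percentile, on the brighter array of a comparison.

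Probe sets were named through a probe set table of the array, which listed 42898 of them. Of these, 41097 had 1 gene symbol and were used, and 1801 had several and were left out. The other 11721 probe sets were not listed and carry no gene name here. Symbols of 41043 probe sets were brought up to date through their gene numbers in the RefSeq gene table of assembly GRCh38.p14. Where a gene had several probe sets, the probe set with the highest mean over the 4 arrays stood for it, which gave 19775 genes.

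The comparisons were each clone with against without doxycycline, the difference between these log2 ratios (EWS/NOR1 clone less NOR1 clone), and the uninduced EWS/NOR1 clone against the uninduced NOR1 clone. Genes at least 2-fold higher or lower were counted. With 1 array per group there is no replicate check, no test between groups was run and no p-value is given, and the number of arrays limits the precision of every value. The spreads given are those between probe sets of the same gene and over spiked control probe sets.

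The settings, the genes to name, the gene lists and all alternatives were chosen before the data were examined. Genes named for an induction were the 8 with the highest and the 8 with the lowest ratio among genes above the floor on both arrays and bright on at least 1, and the 3 largest bounds in each direction. The 5 genes furthest in each direction were named for the difference between the inductions and for the difference between the clones, and up to 4 measured members with the largest ratios were named from each gene list, besides NR4A1, NR4A2, NR4A3 and EWSR1. Genes with placeholder symbols, XIST and Y-linked genes were counted but not named.

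The 36 gene lists held 697 different genes, of which 641 were on the array under 1 symbol and 56 were not analysed here. The median log2 ratio of the measured members of a list was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list with at least 5 measured members stood apart when its median lay below percentile 2.5 or above percentile 97.5. Genes of a pathway vary together, so this describes these arrays and does not test the induction.

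The alternatives were the deposited signals without further scaling, scaling to the same median, quantile normalization, and a loess fit of log2 ratio on mean signal with a span of 0.3. Others were floors at the 30th and the 70th percentile, the floor as a pseudocount, the mean or the median over the probe sets of a gene, and leaving out probe sets whose identifiers end in _x_at or _s_at. For the lists, members above the floor on every array compared were also taken alone. That makes 10 alternatives for genes and 11 for lists, and 2000 random lists were drawn in each alternative.

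The steps were tested on simulated data for the NOR1 induction, with 12798 genes and noise of 0.25 (SD, log2). Of 100 genes simulated with a 3-fold difference, 97 were recovered, and of 100 with a 5-fold difference, 100 were. Among 12598 genes simulated without a difference, 55 were called, or 0.44%. The same noise was used at all signals, and recovery of genes that were not bright was not tested. These rates therefore need not hold for dim genes. In the data, 189 of the 418 genes higher after NOR1 induction and 30 of the 87 lower were bright. Of 200 random lists, 5 stood apart, and all 50 lists raised by 0.4 did.

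Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.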

Results

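Transcript levels were measured on 4 arrays in human 293 cells, an embryonic kidney line transformed with adenovirus DNA. The cells held the tet-On system, in which doxycycline switches on an inserted gene. One clone carried NOR1 (NR4A3), an orphan nuclear receptor of the NR4A family. The other carried EWS/NOR1, a fusion of the RNA-binding protein EWS to NOR1 that is known from extraskeletal myxoid chondrosarcoma. Each clone was profiled without and with doxycycline, with 1 array each, so every ratio below comes from a pair of arrays without replicates. Between 48.3% and 51.0% of the probe sets lay above the floor of 22.6 on each array. The 3' to 5' signal ratio of actin was 1.42 and 1.59 in the NOR1 clone without and with doxycycline, and 1.47 and 1.39 in the EWS/NOR1 clone, and that of GAPDH was 1.06 and 1.09, and 1.09 and 1.04. The 42 spiked control probe sets with signal differed with an SD of 0.16 (log2) between the arrays of the NOR1 clone and 0.14 between those of the EWS/NOR1 clone, and 0 of them differed 2-fold.

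The array did not show the inserted genes. All 3 probe sets of NR4A3 lay at or under the floor in both arrays of the NOR1 clone, with 14.9 without and 22.2 with doxycycline on probe set 207978_s_at. In the EWS/NOR1 clone the only one above the floor was 209959_at, at 29.4 without and 18.4 with doxycycline. Where these probes lie relative to the inserted sequences is not known, so they neither show nor exclude induction. EWSR1, which encodes EWS, had a log2 ratio of 0.12 after NOR1 induction and -0.05 after EWS/NOR1 induction. NR4A2, a relative of NOR1, gave -0.42 and -0.97. NR4A1 showed no clear direction in the NOR1 clone: probe set 210226_at went from 5.48 without to 31.5 with doxycycline, and 202340_x_at from 43.4 to 10.5.

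The first comparison asked which transcripts NOR1 induction affects. Among measured genes that were bright and above the floor on both arrays, SMPX, a small protein of striated muscle, had the largest ratio, 11.9-fold higher with doxycycline (signal 30.8 to 368, probe set 219772_s_at). INHBE, an inhibin beta subunit, was 9.93-fold higher (39.0 to 387, 210587_at). CTH, the enzyme that releases cysteine from cystathionine, was 7.81-fold higher (259 to 2025, 217127_at), and CHAC1, which degrades glutathione, was 6.88-fold higher. FUT1, a fucosyltransferase, and KLHL41, a kelch protein of the sarcomere, were 6.71-fold and 6.68-fold higher. ZFP69B and HEXIM2, an inhibitor of a transcription elongation kinase, were 6.02-fold and 4.68-fold higher, although the other probe set of HEXIM2 had a log2 ratio of only 0.20. The hormone gene FGF21 was at least 5.20-fold higher, ACTN2, an actinin of muscle Z discs, at least 4.97-fold and the RNA gene PARAIL at least 4.56-fold, each with the uninduced array at or under the floor.

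Lower signals with doxycycline in the NOR1 clone were fewer and smaller. LRATD1 was 3.80-fold lower (172 to 45.2, 225667_s_at), and the chemokine receptor gene CXCR4 was 3.29-fold lower (611 to 185, 217028_at). ZCCHC12 was 3.27-fold lower and TMEM126A, a protein of mitochondria, 2.84-fold lower. INSIG1, which holds back the activation of cholesterol synthesis, was 2.64-fold lower (2644 to 1003), and the secreted protease gene ADAMTS1 was 2.63-fold lower. KLRK1-AS1 and LRP3 were each 2.68-fold lower. GPRIN1, SPINK2 and RASD1 were at least 3.55-fold, 2.41-fold and 2.35-fold lower, with the induced array at or under the floor. LRATD1, LRP3 and RASD1 were also at least 2-fold lower in the uninduced EWS/NOR1 clone than in the uninduced NOR1 clone. For these genes the induction cannot be told from the shared uninduced NOR1 array standing high. Of 13301 measured genes, 418 were at least 2-fold higher and 87 at least 2-fold lower, and 189 and 30 of them were bright. At least 4-fold, 23 genes were higher and 0 lower. The log2 ratios of different probe sets of a gene had a median SD of 0.18 over 5969 genes, and in 156 of 168 genes at least 2-fold different with other probe sets above the floor, the median of those went the same way, in 72 of them at least 2-fold. With the mean over probe sets GPRIN1 had a log2 ratio of -0.91, LRP3 -0.60 and LRATD1 -0.52, and without probe sets ending in _x_at or _s_at LRATD1 had -0.05 and ACTN2 0.56. With the floor at the 70th percentile 159 genes were higher and 24 lower, and CHAC1, ZFP69B, LRATD1, KLRK1-AS1 and all 6 genes given as bounds were under 2-fold.

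Genes of the ATF4 and amino acid response were higher as a group after NOR1 induction: of 28 measured members, 18 were at least 2-fold higher, 0 at least 2-fold lower and 10 neither, and 27 had a log2 ratio above 0. Besides CTH, CHAC1 and FGF21, they included STC2, a secreted glycoprotein, at 4.15-fold. The median log2 ratio of the list was 1.13, at percentile 100 of matched random lists, whose medians ran from -0.18 to 0.10. The list stood apart under all 11 alternatives, with medians between 1.03 and 1.19.

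A further 7 lists of the 33 with at least 5 measured members stood apart after NOR1 induction, 5 of them lower, where chance gives 1.6 lists in all for independent lists. Cholesterol synthesis and uptake genes had a median of -0.26 (percentile 1.29): of 15 members, 0 were at least 2-fold higher, INSIG1 and the isoprenoid isomerase gene IDI1 (-1.02) were at least 2-fold lower and 13 were neither, and all 15 lay below 0. IDI1 was under 2-fold in several alternatives, with -0.13 without probe sets ending in _x_at or _s_at. NSDHL, a demethylation enzyme of the pathway, had -0.99 and the synthase gene HMGCS1 -0.91. Genes of mitochondrial ribosomes and translation had a median of -0.23 with 0 of 24 members at least 2-fold different, led by MRPL24 at -0.84. Genes of the G2 and M phases had a median of -0.24 with 0 of 22 members 2-fold different, and UBE2C (-0.65), CENPE (-0.56) and PLK1 (-0.44) were among the lowest. The oxidative stress and metallothionein list had a median of -0.23, with 1 of 13 members at least 2-fold higher, the cystine carrier gene SLC7A11 at 1.94, 1 lower, the heme-degrading enzyme gene HMOX1 at -1.45, and 11 neither. The neuronal and neuroendocrine list had a median of -0.18 although 5 of its 22 members were at least 2-fold higher and 1 lower, with 16 neither: the granule protein genes SCG2 (1.90) and SCG5 (1.80) stood at the top. Splicing factors had a median of 0.06, and -0.039 with arrays scaled to the same median, where the median of all genes was -0.083 and the list still stood apart. In this list 0 of 18 members were 2-fold different, with the kinase genes CLK4 at 0.58 and CLK1 at 0.54. Interferon-stimulated genes had a median of 0.40 with 0 of 18 members 2-fold different, among them PSMB8 (0.95) and IRF7 (0.59). Without probe sets ending in _x_at or _s_at the cholesterol list still stood apart and the other 6 did not, and the interferon list stood apart in 2 of the alternatives. The oxidative stress and neuronal lists also lay lower in the uninduced EWS/NOR1 clone than in the uninduced NOR1 clone, at -0.23 and -0.31, so these results share the uninduced NOR1 array and the induction cannot be told from that array standing high. With the floor at the 70th percentile HMOX1, SCG2 and SCG5 were under 2-fold. The induced NOR1 array had the highest actin 3' to 5' ratio of the 4 arrays, 1.59, but not the highest of GAPDH.

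**Figure D1:**
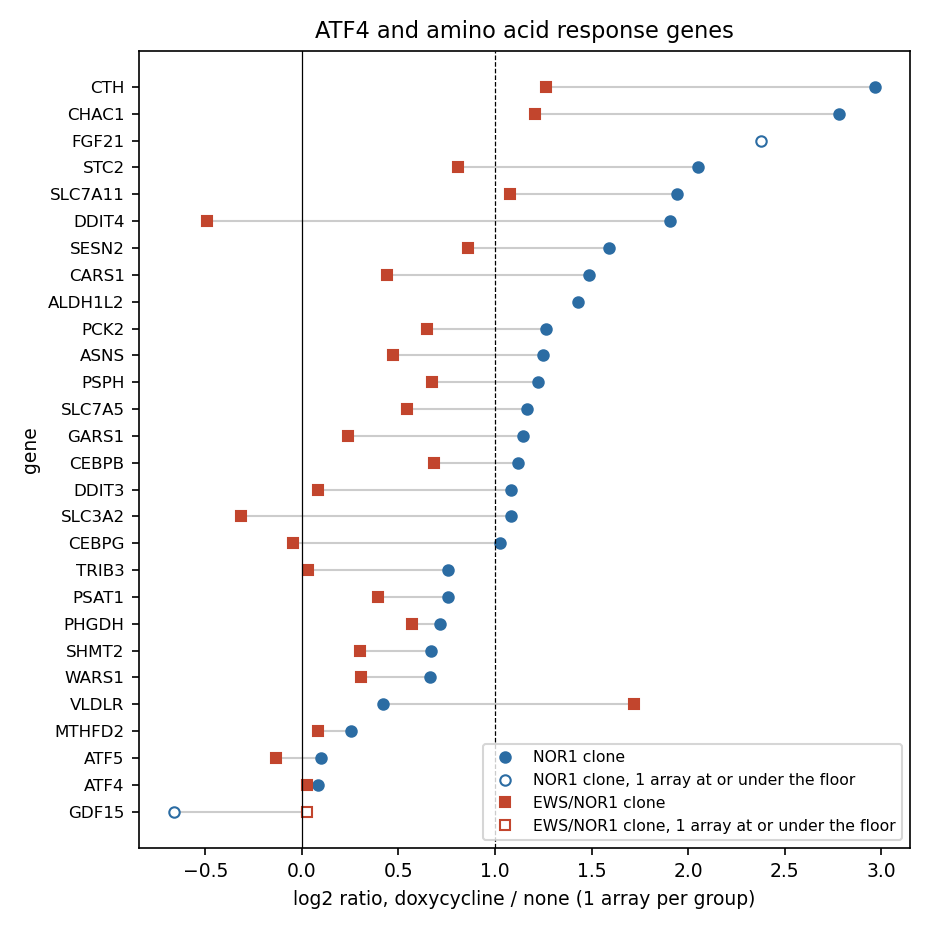
Log2 ratio with over without doxycycline of each measured gene of the ATF4 and amino acid response list, in the NOR1 clone (circles) and the EWS/NOR1 clone (squares), 1 pair of arrays each; open symbols have 1 array at or under the floor and are bounds. CTH lay at 2.97 in the NOR1 clone and at 1.26 in the EWS/NOR1 clone, and DDIT4 at 1.91 and -0.49.

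The same question was asked of EWS/NOR1. SMPX again had the largest ratio among bright genes above the floor on both arrays, 18.6-fold higher with doxycycline (27.8 to 517). ELMOD1 was 10.5-fold higher (79.8 to 836, 231930_at), and SPOCK1, an extracellular proteoglycan, 9.32-fold higher (35.3 to 329, 202363_at). KLHL41 was 8.90-fold and CCDC68 8.80-fold higher. FST, which binds and blocks activin, was 8.37-fold higher (73.5 to 616, 204948_s_at), OLIG1, a transcription factor of oligodendrocytes, 8.34-fold, and DKK1, a secreted inhibitor of Wnt signalling, 7.96-fold (24.5 to 195, 204602_at). The semenogelin genes SEMG2 and SEMG1, which encode proteins of seminal fluid, had log2 ratios of at least 4.17 and 4.07, with induced signals of 408 and 381. The synaptic vesicle gene SV2B was at least 8.43-fold higher.

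TNFRSF12A, a receptor of the tumor necrosis factor family, was 4.61-fold lower with doxycycline in the EWS/NOR1 clone (825 to 179, 218368_s_at). The keratin gene KRT19 was 3.65-fold lower (988 to 271, 201650_at), KLRK1-AS1 3.43-fold and FOSL2, a subunit of the AP-1 transcription factor, 3.42-fold. The receptor gene IL6R and the transcription factor gene SOX11 were 2.87-fold and 2.86-fold lower, CYP4X1 2.83-fold and CXCR4 2.79-fold (511 to 183). ADAM33, PRKCD and ZNF414 were at least 4.04-fold, 3.35-fold and 2.64-fold lower. Of 13058 measured genes, 337 were at least 2-fold higher and 82 at least 2-fold lower, and 147 and 38 of them were bright. At least 4-fold, 47 genes were higher and 2 lower. Probe sets of a gene had a median SD of 0.17 over 5871 genes, and in 132 of 143 genes at least 2-fold different the median of the other probe sets went the same way, in 64 of them at least 2-fold. With arrays scaled to the same median, which put the median of all genes at -0.19, 222 genes were higher and 178 lower. KRT19, FOSL2 and ZNF414 were under 2-fold with the mean over probe sets (-0.93, -0.72 and -0.70), SV2B with the median over probe sets (0.26), and DKK1, FOSL2, SV2B, ADAM33, PRKCD and ZNF414 with the floor at the 70th percentile.

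After EWS/NOR1 induction 15 of 33 lists stood apart, 9 higher and 6 lower, where chance gives 1.6 for independent lists. Genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.43, at percentile 100: all 16 members lay above 0, with 0 at least 2-fold different. They included XBP1, its transcription factor (0.77), and the folding protein genes PDIA4 (0.71) and HYOU1 (0.59). ATF4 and amino acid response genes had a median of 0.42, with 4 of 26 members at least 2-fold higher, 0 lower and 22 neither. VLDLR (1.72), CTH (1.26), CHAC1 (1.21) and SLC7A11 (1.08) were the 4. Targets of p53 had a median of 0.38 with 0 of 17 members 2-fold different: the stress gene SESN2 had 0.86 and the death receptor gene FAS 0.77, but the cell cycle inhibitor gene CDKN1A had -0.84. The p53 targets also lay at -0.30 in the uninduced EWS/NOR1 clone against the uninduced NOR1 clone and did not stand apart in the difference between the inductions (0.12), so the induction cannot be told from the shared uninduced EWS/NOR1 array standing low. These 3 lists stood apart under all 11 alternatives. CHAC1 and SLC7A11 were under 2-fold with the floor as a pseudocount, CHAC1 also with the floor at the 70th percentile, and SLC7A11 with arrays scaled to the same median and with the mean over probe sets.

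Genes described as expressed in extraskeletal myxoid chondrosarcoma had a median of 0.54 in the EWS/NOR1 clone, at percentile 99.9. Of 10 members, 2 were at least 2-fold higher, DKK1 and the neuroendocrine transcription factor gene INSM1 (1.45), 0 were lower and 8 were neither, with the receptor gene RET at 0.90. Between the uninduced clones the list lay at -0.24 in the EWS/NOR1 clone, within the range of random lists, with 8 of 10 members below 0. Part of the 0.54 therefore cannot be told from the uninduced EWS/NOR1 array standing low. After NOR1 induction the same list had a median of 0.02, within the range of random lists. RET, at least 1.06, was then the 1 of 11 members at least 2-fold higher, DNER the 1 at least 2-fold lower, and 9 were neither. RET was under 2-fold in several alternatives, with 0.53 with the mean over probe sets and 0.97 with arrays scaled to the same median. DNER had -0.855 with the floor as a pseudocount. Genes described as NR4A receptor targets had a median of 0.40 after EWS/NOR1, with 2 of 11 members at least 2-fold higher, the muscle enolase gene ENO3 (2.43) and the mitochondrial carrier gene UCP2 (1.40), and 9 neither. They did not stand apart after NOR1 induction, at 0.17. There 2 of 10 members were also at least 2-fold higher, ENO3 and RET, 1 was at least 2-fold lower and 7 were neither. ENO3 had 1.17 after NOR1 induction, and 0.59 with the mean over probe sets. UCP2 was also at least 2-fold lower in the uninduced EWS/NOR1 clone than in the uninduced NOR1 clone, and at -0.97 there with the loess fit. Its ratio after EWS/NOR1 induction therefore cannot be told from the uninduced EWS/NOR1 array standing low. Genes described as EWS/FLI1 targets had a median of 0.33, with 1 of 14 at least 2-fold higher, PPP1R1A, and 13 neither. They had a median of -0.37 in the uninduced EWS/NOR1 clone against the uninduced NOR1 clone, so the induction cannot be told here either from the uninduced array standing low. With the floor at the 70th percentile the NR4A target median was -0.12 and the EWS/FLI1 target median -0.086, and neither stood apart, nor did they with the mean over probe sets, where INSM1 (0.73), UCP2 (0.77) and PPP1R1A (0.59) were under 2-fold.

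Growth factors and their receptors had a median of 0.29 after EWS/NOR1 induction, with 3 of 26 members at least 2-fold higher and 23 neither. The stem cell factor receptor gene KIT had 2.07, its ligand gene KITLG 1.27 and TGFA 1.21. Without probe sets ending in _x_at or _s_at this list had 0.26 and did not stand apart. Axon guidance genes had a median of 0.33, with 3 of 23 at least 2-fold higher and 20 neither: NTN4, a netrin, had 1.72, the plexin gene PLXNC1 1.46 and the netrin receptor gene UNC5C 1.22. Cholesterol genes had a median of 0.19, and -0.0053 with arrays scaled to the same median, where the median of all genes was -0.19 and the list still stood apart from random lists. Of its 15 members 1 was at least 2-fold higher, the sterol carrier gene STARD4, 2.83-fold, and 14 were neither. The axon guidance list did not stand apart with the floor at the 30th percentile or with the mean or the median over probe sets. TGFA, PLXNC1 and UNC5C were under 2-fold with the mean over probe sets, and NTN4 with the floor at the 70th percentile.

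Lower as groups after EWS/NOR1 induction were immediate early genes, with a median of -0.61 at percentile 0. Of 19 members 2 were at least 2-fold lower, DUSP1 (-1.13) and ATF3 (-1.07), 15 were neither and 2 were at least 2-fold higher, the phosphatase genes DUSP6 (1.29) and DUSP5 (1.06). A list of short-lived transcripts that are lost with RNA handling, which shares members with it, had a median of -0.65. All 11 of its members lay below 0, with KLF6 and IER3 at -0.93 each, and it lay at 0.02 in the NOR1 clone. With 1 culture per group, the lower values of both lists cannot be told from the handling of the induced EWS/NOR1 culture or its RNA. None of the alternatives bears on handling. Wnt and Notch targets had a median of -0.48, with 1 of 15 at least 2-fold lower, HEY1 (-1.09), 2 at least 2-fold higher, DKK1 and HEYL (1.26, and 0.63 with the mean over probe sets), and 12 neither. HES1, a Notch target, had -0.81. Epithelial genes had a median of -0.34, with KRT19 the 1 of 10 at least 2-fold lower and KRT8 at -0.62. Genes of mitochondrial ribosomes and translation had a median of -0.30 with 0 of 24 members 2-fold different, and heat shock proteins -0.22 with 0 of 14, including HSF1 at -0.80 and HSPB1 at -0.72. Immediate early genes, short-lived transcripts, Wnt and Notch targets and mitochondrial translation stood apart under all 11 alternatives. The epithelial and heat shock lists did not without probe sets ending in _x_at or _s_at, ATF3 was at -0.57 there, and ATF3 and DUSP1 were at -0.77 and -0.85 with the mean over probe sets. DUSP6 was at 0.84 with the floor at the 70th percentile, and DUSP5 at 0.87 with arrays scaled to the same median.

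**Figure D2:**
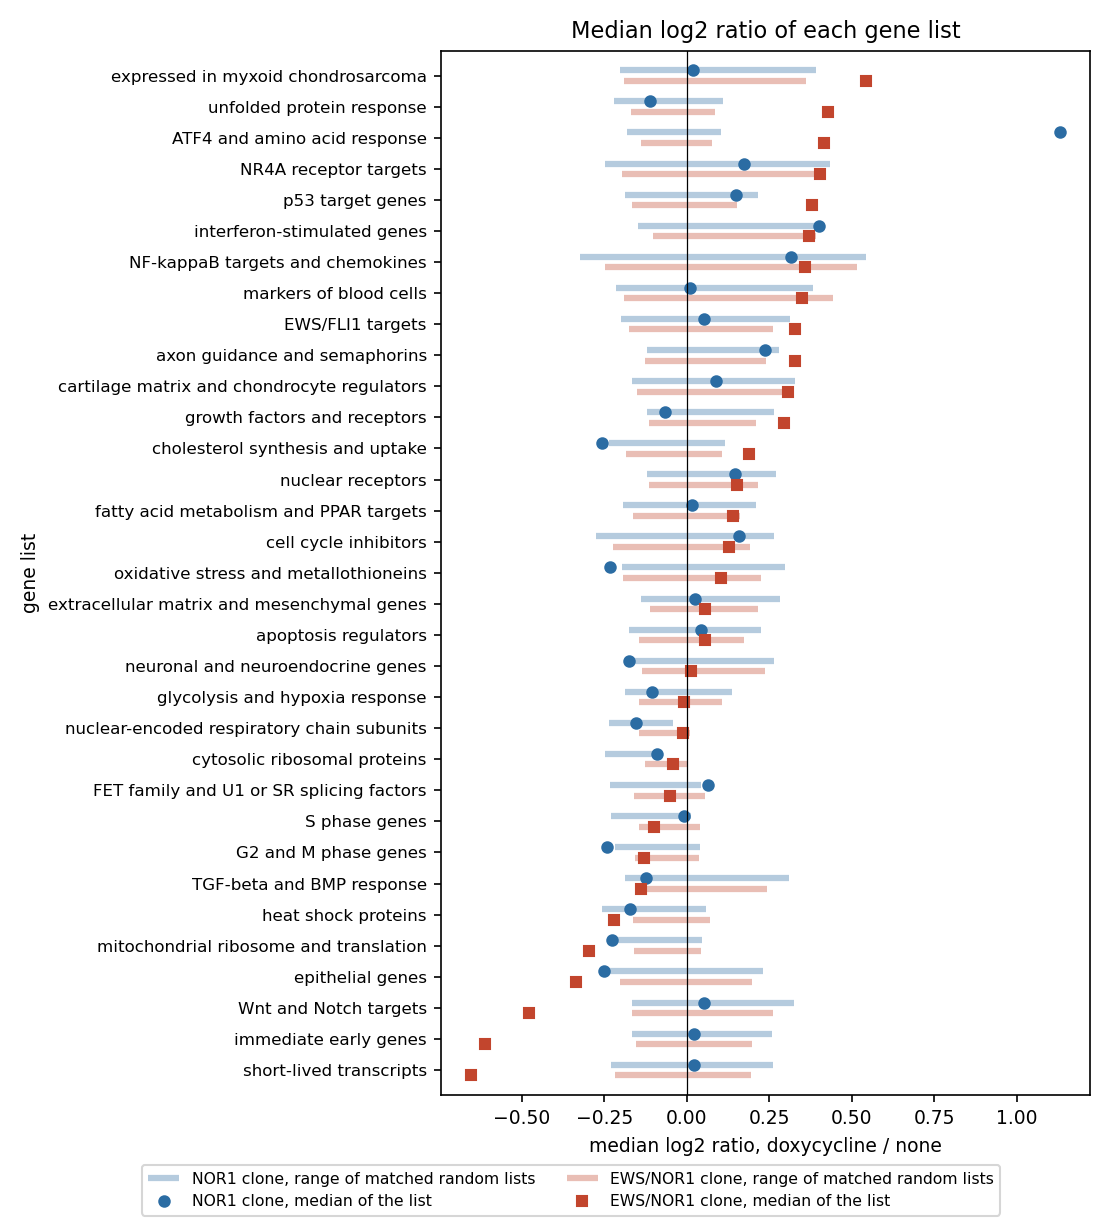
Median log2 ratio, with over without doxycycline, of the measured members of each of 33 gene lists in the NOR1 clone (circles) and the EWS/NOR1 clone (squares); bars span the range of matched random lists outside which a list stood apart. The ATF4 list lay at 1.13 in the NOR1 clone, and the list of short-lived transcripts at -0.65 in the EWS/NOR1 clone.

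Both inductions were then set side by side. SMPX, KLHL41, CTH, CHAC1 and FUT1 were at least 2-fold higher with doxycycline in both clones, as were ACTA2, the actin of smooth muscle (3.98-fold and 3.42-fold), and KITLG (3.03-fold and 2.41-fold). CXCR4, KLRK1-AS1, TNFRSF12A and ADAMTS1 were at least 2-fold lower in both. Of 12493 genes measured in both clones, 53 were at least 2-fold higher in both, of 403 and 319 in each, where 10.3 would be shared by independent lists. A further 15 were lower in both, of 81 and 82, against 0.53. Across these genes, which are not independent replicates, the log2 ratios of the inductions had a Pearson r of 0.27 and a Spearman rho of 0.24, and the inductions share no array. Both clones received doxycycline, and no cells without an inserted gene were profiled. Changes shared by the clones, of genes or of lists, therefore cannot be told from a response to doxycycline itself. ACTA2 was under 2-fold in both clones with the mean or the median over probe sets, and so was ADAMTS1 after EWS/NOR1 (-0.93). After EWS/NOR1 CHAC1 and FUT1 were under 2-fold with the floor as a pseudocount or at the 70th percentile, and FUT1 with arrays scaled to the same median (0.94) and with quantile normalization (0.97). In all, 226 genes went the same way with the floor at the 30th percentile but 27 with it at the 70th.

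**Figure D3:**
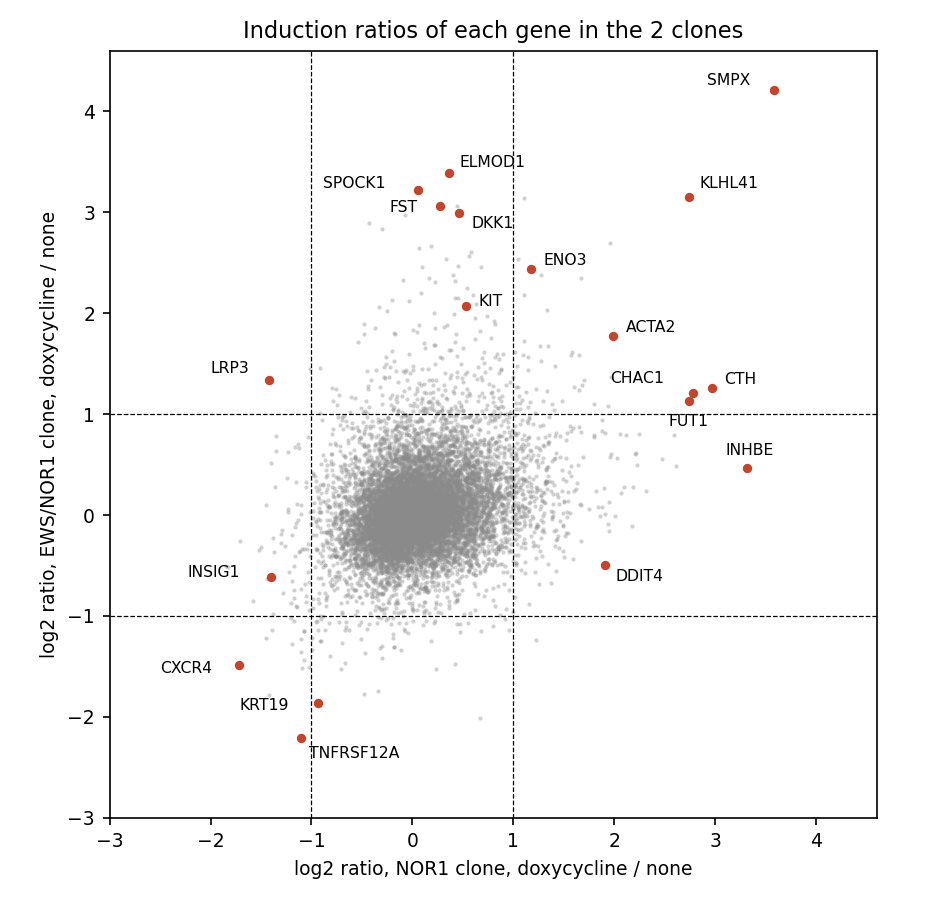
Log2 ratio with over without doxycycline of 12493 genes in the NOR1 clone (x axis) and the EWS/NOR1 clone (y axis), 1 point per gene, with dashed lines at 2-fold and some of the named genes in red. SMPX lay at 3.58 and 4.22, SPOCK1 at 0.06 and 3.22, and INHBE at 3.31 and 0.47.

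The series also asks how NOR1 and EWS/NOR1 differ, which was read as the log2 ratio of the EWS/NOR1 clone less that of the NOR1 clone. SPOCK1 had the largest difference among bright genes above the floor on all 4 arrays, 3.16, with 3.22 in the EWS/NOR1 clone and 0.06 in the NOR1 clone. MTSS1 followed at 3.04, ELMOD1 at 3.02, FST at 2.80 and LRP3, which was lower after NOR1 and higher after EWS/NOR1, at 2.77. MTSS1 and LRP3 already lay lower in the uninduced EWS/NOR1 clone than in the uninduced NOR1 clone, at -1.47 and -1.82 (log2). Between the induced arrays they lay higher in the EWS/NOR1 clone, at 1.57 and 0.95. Part of their values therefore cannot be told from a difference before induction. In the other direction INHBE had -2.84. DDIT4, an inhibitor of the growth kinase mTOR, had -2.40, with 735 to 2752 in the NOR1 clone and 552 to 393 in the EWS/NOR1 clone. THAP9-AS1 had -2.10, DUSP28 -2.03 and HEY2, a Notch target, -1.85. DUSP28 already lay higher in the uninduced EWS/NOR1 clone, at 0.99, so the same limit holds for it. Of 13866 measured genes, 414 had a difference of at least 1 (log2) and 432 of -1 or less. The counts were 323 and 541 with arrays scaled to the same median, which put the median of all genes at -0.10, and 116 and 178 with the floor at the 70th percentile. These differences combine 4 single arrays and were not tested. MTSS1 had 0.66 without probe sets ending in _x_at or _s_at, and 0.74 with the mean and 0.00 with the median over probe sets. With the mean LRP3 was under 2-fold in both clones.

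Of 34 lists, 11 stood apart in the difference between the inductions, 7 higher after EWS/NOR1 and 4 lower, where chance gives 1.7 for independent lists. ATF4 and amino acid response genes had a median difference of -0.73: 9 of 28 members had a difference of -1 or less, 1 of at least 1 and 18 neither. Cholesterol genes had 0.58, with 2 of 15 members at 1 or more, STARD4 (1.76) and NSDHL (1.38), and 13 neither. Genes of the unfolded protein response had 0.40, with 2 of 16 at 1 or more, CRELD2 (1.15) and PDIA4 (1.02). Genes described as expressed in extraskeletal myxoid chondrosarcoma had 0.49, with 3 of 11 at 1 or more, DKK1 (2.53), DNER (1.84) and INSM1 (1.30). DNER was at least 2-fold lower after NOR1 induction and under 2-fold after EWS/NOR1 induction. Short-lived transcripts had -0.68, with ATF3 at -1.62, and the handling of the induced EWS/NOR1 culture cannot be told apart here either. These 5 lists stood apart under all 11 alternatives, but DKK1, DNER and INSM1 lay under 1 with the floor at the 70th percentile and PDIA4 with arrays scaled to the same median. The lists of NR4A targets (0.55), EWS/FLI1 targets (0.36), oxidative stress and metallothioneins (0.43), growth factors (0.31), S phase genes (-0.15) and splicing factors (-0.13) also stood apart, each with at least 1 alternative in which it did not. The EWS/FLI1 target and oxidative stress lists already lay lower in the uninduced EWS/NOR1 clone (-0.37 and -0.23), and those arrays enter the difference, so it cannot be told from a difference before induction. The myxoid chondrosarcoma list lay at -0.24 there, within the range of random lists, so part of its difference has the same limit.

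The clones were also compared without doxycycline, which gives the size of differences that are present before induction. CD99, a cell surface glycoprotein, was 20.6-fold lower in the EWS/NOR1 clone (905 against 43.9, 201029_s_at). The transcription factor gene EBF3, the RNA-binding protein gene RBM24, the trypsinogen gene PRSS3 and LRP3 were 4.94-fold, 4.63-fold, 4.31-fold and 3.52-fold lower. DECR1, a mitochondrial enzyme of fatty acid oxidation, was 8.22-fold higher in the EWS/NOR1 clone (25.7 against 211, 202447_at), TCEAL7 4.72-fold and the calcium channel subunit gene CACNG4 3.31-fold. The zinc finger genes ZNF22 and ZNF532 were 2.55-fold and 2.45-fold higher, and ZNF532 lies on chromosome 18, whose genes had a median log2 ratio of 0.40. Of 12934 measured genes, 40 were at least 2-fold higher and 210 at least 2-fold lower in the EWS/NOR1 clone. With the deposited signals these counts were 23 and 324, and the median of all genes was -0.15, and with arrays scaled to the same median they were 77 and 144. EBF3 had a log2 ratio of 0 without probe sets ending in _x_at or _s_at, where ZNF532 had 0.80, and with the mean over probe sets CACNG4 had 0.58 and LRP3 -0.95. With the floor at the 70th percentile EBF3, PRSS3 and CACNG4 were under 2-fold.

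Between the uninduced clones 9 of 33 lists stood apart, 8 of them lower in the EWS/NOR1 clone, where chance gives 1.6 for independent lists. Targets of p53 had a median of -0.30 with 0 of 17 members 2-fold different, and stood apart under all 11 alternatives. Neuronal and neuroendocrine genes had a median of -0.31, with 1 of 21 at least 2-fold lower, the neurofilament gene NEFM (-1.47, and -0.73 with the mean over probe sets), and 20 neither. The other 6 lower lists were EWS/FLI1 targets (-0.37), apoptosis regulators (-0.24), short-lived transcripts (-0.24), oxidative stress and metallothioneins (-0.23), immediate early genes (-0.21) and cell cycle inhibitors (-0.20). Axon guidance genes had a median of 0.12, and -0.026 with the deposited signals, where the median of all genes was -0.15 and the list still stood apart. It did not with either other floor, with the mean or the median over probe sets or without probe sets ending in _x_at or _s_at. The oxidative stress list had 0.042 with arrays scaled to the same median, and each of these lists other than that of p53 targets failed to stand apart in at least 1 alternative.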

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

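The genes and probe sets below were picked out only after their values were seen. CLBA1, FKBP10 and LRP3 were at least 2-fold different in opposite directions in the clones, and each clone gave 1 pair of arrays, so the difference was not tested. CLBA1 had a log2 ratio of 1.22 after NOR1 induction (37.4 to 87.4) and -1.24 after EWS/NOR1 induction (71.8 to 30.5). FKBP10 had a log2 ratio of -1.01 or lower after NOR1 induction and 1.44 or higher after EWS/NOR1 induction, each against an array at or under the floor (45.7 to 22.3, and 8.14 to 61.6). LRP3 had a log2 ratio of -1.42 after NOR1 induction and 1.34 after EWS/NOR1 induction. Its other probe set above the floor had 0.23 after NOR1 induction, and with the mean over probe sets LRP3 was under 2-fold in both clones (-0.60 and 0.97). All 3 genes already differed between the uninduced NOR1 and EWS/NOR1 clones. Signals there were 37.4 against 71.8 for CLBA1 and 45.7 against 8.14 for FKBP10, and LRP3 had a log2 ratio of -1.82. The opposite directions therefore cannot be told from the uninduced arrays standing high or low for these genes.

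Of the 11721 probe sets without a gene name here, which no comparison used, 3141 were above the floor on at least 1 array of each induction. After NOR1 induction 70 of them were at least 2-fold higher and 30 lower, and after EWS/NOR1 induction 70 were higher and 23 lower. Probe set 1555743_s_at had the highest log2 ratio after NOR1 induction among those bright and above the floor on both arrays, 2.41 (64.5 to 344). Probe set 230319_at had the highest after EWS/NOR1 induction, 2.76 (32.8 to 222).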

How the results depend on the processing

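All alternatives and results in this part were planned before the data were examined. With 1 array per group, no setting can show how far a ratio would vary between cultures, and the floor sets how much signal over background a ratio needs. Counts depend most on it, since a lower floor admits dimmer genes and larger ratios among them. Unless the construction of a setting shows the cause, the cause was not tested. Pairs of counts are genes at least 2-fold higher and lower, for NOR1 induction, EWS/NOR1 induction, the difference between them and the uninduced clones in turn. Values outside 1.5 times the main count are given, and for a list or gene each value whose sign turned.

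With the floor at the 30th percentile the pairs were 1036 and 507, 1111 and 462, 1385 and 1239, and 409 and 882. There 226 genes went the same way in both inductions, and their correlation was 0.15. With the floor at the 70th percentile the pairs were 159 and 24, 116 and 35, 116 and 178, and 7 and 27, and 27 genes went the same way. Medians after EWS/NOR1 induction there were -0.12 for genes described as NR4A receptor targets (main 0.40) and -0.086 for genes described as EWS/FLI1 targets (main 0.33), and HRK had a difference between the inductions of 0.30 (main -1.12). With the floor as a pseudocount 246 genes were higher after NOR1 induction, 47 lower after EWS/NOR1 induction, 120 lower in the uninduced EWS/NOR1 clone and 41 the same way in both inductions.

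With the mean over probe sets the pairs were 252 and 53, 181 and 36, 216 and 244, and 18 and 94, with 40 genes the same way in both inductions. Axon guidance genes had a median of -0.011 between the uninduced clones (main 0.12). With the median over probe sets the pairs were 264 and 53, 187 and 40, 219 and 258, and 18 and 95, with 44 the same way. Without probe sets ending in _x_at or _s_at PLXNA1 had 0.54 after NOR1 induction (main -1.06), since another of its probe sets was then read.

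With arrays scaled to the same median 132 genes were lower after NOR1 induction, 222 higher and 178 lower after EWS/NOR1 induction, and 77 higher in the uninduced EWS/NOR1 clone. That scaling put the median of all genes at -0.083 after NOR1 induction, -0.19 after EWS/NOR1 induction and -0.10 in the difference. The share of higher genes among those 2-fold different was 69.2% after NOR1 induction (main 82.8%), 55.5% after EWS/NOR1 (main 80.4%), 37.4% in the difference (main 48.9%) and 34.8% between the clones (main 16.0%). It was 71.7%, 69.3% and 29.7% with quantile normalization after NOR1 induction, after EWS/NOR1 induction and between the clones, and 67.1% and 31.7% with the floor at the 30th percentile after NOR1 induction and between the clones. List medians with arrays scaled to the same median were -0.039 for splicing factors after NOR1 induction (main 0.06), -0.0053 for cholesterol genes after EWS/NOR1 induction (main 0.19) and 0.042 for oxidative stress genes between the clones (main -0.23). The splicing and cholesterol lists still stood apart there, since the scaling moved all genes alike, and the oxidative stress list did not. MT1E, near the floor, had 0.79 between the clones (main -1.01) and -0.21 in the difference (main 1.03), and with quantile normalization 0.77 and -0.17. The median of all genes between the clones moved only from -0.02 to 0.09 with median scaling, too little to turn MT1E. With the mean over probe sets MT1E had -0.17 between the clones, and which probe set was read in each setting was not checked. The oxidative stress list holds MT1E. Quantile normalization gave 63 genes higher in the uninduced EWS/NOR1 clone. With the deposited signals 23 genes were higher and 324 lower in it, 6.63% of these higher, the median of all genes was -0.15 and that of axon guidance genes -0.026, which still stood apart.

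Over all values, those given above included, the direction and the side of the threshold were kept as follows. Of 2172 values of 222 ratios that were at least 2-fold, 1773 stayed at least 2-fold the same way, and 77 ratios did so in every alternative. Of 472 values of 43 list medians that stood apart, 386 stayed apart the same way, and 16 of these medians did so in every alternative. Of 950 values of 90 list medians that did not stand apart, 904 stayed so, and of 7621 values of 783 ratios under 2-fold, 7516 did.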

Other observations

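All 3 patterns weighed in this part, and the tests of each, were chosen only after the result was seen, while the gene lists were planned. Genes of the extracellular matrix and of mesenchymal cells did not stand apart as a list in either clone, with medians of 0.02 after NOR1 induction and 0.06 after EWS/NOR1 induction. Some members had large ratios: after EWS/NOR1 induction the fibronectin gene FN1 had 2.54 (197 to 1145), the thrombospondin gene THBS1 at least 2.46 and ACTA2 1.78, while the transcription factor gene SNAI2 had -1.36 or lower. FN1 and THBS1 were each at 0.00 without probe sets ending in _x_at or _s_at. Among genes of the TGF-beta and BMP response, the inhibitors of differentiation ID4 and ID2 had -1.21 and -1.16 after NOR1 induction, and ID1 and ID4 had -1.14 and -1.02 after EWS/NOR1 induction (ID1 -0.57 with the floor at the 70th percentile, ID4 -0.82 with the mean over probe sets). The list medians were -0.12 and -0.14, within the range of random lists. Among nuclear receptors the vitamin D receptor gene VDR had -1.23 and the estrogen receptor gene ESR1 at least 1.63 after EWS/NOR1 induction, and NR1H3 had 1.01 after NOR1 induction, in a list with medians of 0.14 and 0.15. With the mean over probe sets VDR had -0.61 and ESR1 0.18, and NR1H3 was under 2-fold in 5 alternatives.

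Genes of glycolysis and the hypoxia response had medians of -0.10 after NOR1 induction and -0.01 after EWS/NOR1 induction. VEGFA had 1.10 after NOR1 induction (0.91 with the mean over probe sets), and NDRG1 and ADM had -1.25 and -1.02 after EWS/NOR1 induction (ADM -0.97 with the deposited signals). Genes of the unfolded protein response had a median of -0.11 after NOR1 induction, within the range of random lists, with XBP1 at 1.31, and at 0.66 with the mean over probe sets. S phase genes had medians of -0.01 and -0.10, cytosolic ribosomal proteins -0.09 and -0.04, and respiratory chain subunits -0.15 and -0.01, none of them apart from random lists of like signal. Among apoptosis regulators, at medians of 0.04 and 0.05, BMF had 1.28 after NOR1 induction, BCL2L1 had 1.18 and HRK -1.42 after EWS/NOR1 induction. BMF had 0.79 with the floor as a pseudocount, and BCL2L1 and HRK had 0.45 and -0.90 with the mean over probe sets. Cartilage genes had medians of 0.09 and 0.31 and did not stand apart, and markers of blood cells had 0.01 and 0.35 and did not either.

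The chromosome 18 genes were brighter in the uninduced EWS/NOR1 clone than in the uninduced NOR1 clone, with a median log2 ratio of 0.40 over 184 genes (quartiles 0.25 and 0.51), where the other chromosomes lay between -0.15 and 0.05. A trend with signal is argued against, since the chromosome 18 median less that of all genes was 0.39 with quantile normalization and 0.41 with the loess fit. Scaling by 1 factor per array cancels in this measure by construction, so the remaining scalings test nothing here. A few genes with large differences are argued against, since 92.4% of the genes lay above 0. The pattern is consistent with clones that differ in the number of copies of chromosome 18: the induced arrays, a pair that shares no array with the uninduced pair, gave 0.29, above the other chromosomes (-0.23 to 0.05), and the medians within the clones were 0.05 and -0.03. No DNA was measured, and the biological difference between the inserted genes before induction stays open and untested.

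The ATF4 and amino acid response genes were higher after NOR1 induction by a median of 1.13. Array scaling is argued against, since the lowest median over the other scalings was 1.03, above random lists of up to 0.10. Doxycycline acting alike in both clones is argued against as the whole cause, since the median difference between the inductions was -0.73, outside random lists of -0.13 to 0.18. The list was also higher after EWS/NOR1 induction, at 0.42, so a part shared by the clones cannot be told from a response to doxycycline. A response to it that differs in size between single cultures was not tested. The state of 1 culture, such as depleted medium, cannot be told apart from the induction with 1 culture per group, whatever the median of glycolysis and hypoxia genes, which was -0.10. An effect of NOR1 itself may also account for the pattern and was not tested apart from the culture.

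Genes whose symbols are ZNF and a number, most of them zinc finger proteins, were higher after NOR1 induction, with a median of 0.34 over 380 genes, 30 at least 2-fold higher, among them ZNF256 (3.58-fold, 116 to 415) and ZNF583 (2.83-fold), and 4 lower. The median was -0.04 over 371 genes after EWS/NOR1 induction, below random lists (0.0069 to 0.099), and 0.05 over 373 genes between the uninduced clones, above them (-0.097 to -0.023). A trend with signal is argued against by the median less that of all genes, 0.27 with quantile normalization and 0.27 with the loess fit. Scaling by 1 factor per array cancels in this measure, which therefore does not test it. Probe sets shared by related genes are argued against by a median of 0.33 over 320 genes without probe sets ending in _x_at or _s_at. The median was 0.34 on chromosome 19 and 0.33 on the others. The RNA quality of the induced NOR1 array cannot be told apart from the induction, since that array alone stands for the induced group, its actin 3' to 5' ratio of 1.59 was the highest of the 4, and its GAPDH ratio was above that of the uninduced NOR1 array (1.09 against 1.06), although the uninduced EWS/NOR1 array had a GAPDH ratio as high (1.09) with a median of only 0.05 against the uninduced NOR1 array. The medians also went the same way as the actin ratio in each comparison. The actin ratio went from 1.42 to 1.59 with NOR1 induction (median 0.34) and from 1.47 to 1.39 with EWS/NOR1 induction (-0.04). Between the uninduced clones it was 1.42 for NOR1 and 1.47 for EWS/NOR1 (0.05). An effect of NOR1 stays open and was not tested apart from RNA quality.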
